A study of Pimephales promelas with 24 samples.

How the data were processed

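The samples were sub-adult fathead minnows (Pimephales promelas), each hybridised to its own 1-colour Agilent microarray with cyanine-3-labelled cRNA. Per the labels, 24 fish fell into 4 groups of 6, crossing the rearing history (0 or 0.83 mg/L RDX) with a 96 h challenge (0 or 5 mg/L RDX) at 90 days after hatching. Group and replicate letter were taken from the sample titles. For 1 control-reared unchallenged fish the title gave replicate E and the description gave B; the title was used, and the array correlated with replicate B at 0.897, below the highest correlation of 2 arrays of a group (0.961), so that it was kept as a separate sample. The labels named the tissue as liver, whereas the series title spoke of whole body and the protocol of bodies split lengthwise, so the tissue was not settled. Fish were exposed singly in beakers, so each array stood for 1 fish.

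Per the file headers, the authors' scanner files held raw and processed spot intensities from Agilent Feature Extraction 9.5.1.1, with background subtraction, spatial detrending and surrogate values for spots near background, and with no normalization between arrays. The deposited value table held log2 values; set against the scanner intensities, they equalled log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 24 arrays, with 100% of values within 0.01 and a lowest array correlation of 1.00. Its scale, centring and direction were thereby found from the data, not from a stated method. The medians of its columns, replicates A to F, were 0.17, -0.02, -0.15, 0.18, -0.31 and -0.05 in control-reared unchallenged fish and -0.06, 0.31, -0.18, -0.14, -0.13 and 0.04 in control-reared challenged fish. They were 0.03, 0.19, -0.30, 0.20, 0.11 and 0.27 in RDX-reared unchallenged fish and -0.19, 0.53, -0.29, 0.44, -0.00 and -0.13 in RDX-reared challenged fish. Spot marks for background, saturation and outliers were deposited as 0 or 1 per spot, per the file headers.

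The array carried 15208 non-control probes of 60 bases, each on 1 spot. Log2 processed signal was taken relative to each array's 75th percentile, control spots were left out, and spots marked as non-uniform or as population outliers (2.25% of spots) were treated as missing. Probes entered the test when well above background on at least 6 of the 24 arrays, which left out 1397. A further 274 were left out because some group kept fewer than 3 unmarked spots, a requirement added once the marks had been seen. The remaining 13537 probes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as 4 group means over all 24 arrays, with 20 residual degrees of freedom before moderation, and 7 contrasts were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A probe not well above background on any array of a group was given only a bound, namely the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value among probes well above background. Principal components used the 12000 tested probes without a missing spot. Whole-profile tests used Euclidean distances and 100000 permutations in vegan 2.7.1.

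All probes were described as unknown in the files, and 0 of the 15208 identifiers, which name source contigs or sequence records, matched the gene table used here (assembly fPimPro1.hap1.1). The 25 gene lists, including cell type markers, and the rule for naming genes fixed before the data were examined therefore could not be applied, and the make-up of the samples was not compared by tissue markers. In place of that rule, every probe past the threshold was named, together with the lowest-p probe among those lower in RDX-reared fish; this choice was made after the values were seen. Probe sequences are given as the array design lists them, and their genome positions were not analysed here.

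The arrays lay on 6 slides read on 4 scan days. Slides 1, 2 and 3 held all 4 groups on 16 arrays and shared a scan day; slide 4 held 1 RDX-reared challenged array, slide 5 held 3 control-reared and 2 RDX-reared unchallenged arrays, and slide 6 held 2 control-reared challenged arrays. Slide was therefore tried as a fixed block, as a random block (duplicateCorrelation, statmod 1.5.0) and within the 3 complete slides. The other alternatives set before the data were examined were quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, the deposited value table, no filter on dim probes, probes well above background on all arrays, a replicate block, array weights, and fits of only the groups compared. Added after seeing the data were the first principal component as a covariate, array weights together with that covariate, outlier spots kept, and the fit without 1 array.

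The fit was tested on simulated data for the challenge effect in RDX-reared fish, with 200 of the 13537 probes changed in 10 simulations. With independent noise of the size seen in each probe, 17.0%, 61.2%, 84.0% and 94.6% of changes of 1, 2, 3 and 4 log2 units were recovered, with a mean of 6.1 false calls. With the measured residuals of whole arrays shuffled, recovery was 14.4%, 60.2%, 86.8% and 94.6%. False calls then averaged 419.7, but nearly all of them came from 1 simulation with 4193, and the others had few. The residuals of different probes move together across arrays, so false calls can come in large numbers at once. These recoveries hold for 200 changed probes. With fewer changed probes the adjusted threshold is stricter, and a lone call needs an unadjusted limma p under 3.69e-06. Recovery of the same changes would then be lower, so these shares are not the power behind contrasts with few or no calls. The number of arrays limits the precision: the median standard error was 0.45 log2 units for a difference of 2 groups, 0.32 for an average effect and 0.64 for the interaction.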

Results

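RDX is a cyclic nitramine explosive that acts on the nervous system, where it blocks GABA type A receptors. Per the design text, fathead minnows were bred for successive generations in clean water or in 0.83 mg/L RDX, and F2 sub-adults of each line, 90 days after hatching, were then held for 96 h in clean water or in 5 mg/L RDX. The stated question was whether the long exposure of a line changed its sensitivity to RDX. Expression was measured in 24 fish, 6 in each of 4 groups, named here by rearing (control-reared or RDX-reared) and by challenge. Between 74.6% and 93.0% of the 15208 probes were well above background on an array, with a median of 83.2%, and between 208 and 413 probes were saturated. The 75th percentile of the processed signal ran from 1759 to 6302 intensity units.

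Most of the variation lay between fish of the same group. The median SD of a probe among the 6 fish was 0.74 log2 units in control-reared unchallenged, 0.76 in control-reared challenged, 0.68 in RDX-reared unchallenged and 0.79 in RDX-reared challenged fish. Values of 616 of the 13537 tested probes (4.55%) spanned over 100-fold across the arrays, and those of 129 spanned over 1000-fold. On a single array up to 63 of those 129 were not well above background and up to 34 were saturated, so these spans are not exact. The first principal component held 48.1% of the variance, and the next held 10.2%. Scores on it reached from -109 to 101, with no array between 8.17 and 81.3; the 9 arrays above that gap came from all groups, namely 2, 2, 3 and 2 in the order control-reared unchallenged, control-reared challenged, RDX-reared unchallenged and RDX-reared challenged. Within a group the scores spanned at least 79.8% of their range over all arrays. Mean scores were -3.55 ± 81.5, -19.7 ± 87.5, 34.6 ± 69.8 and -11.3 ± 81.1 in that order (SD, n = 6 each), a difference smaller than the spread between fish (permutation test over the 4 groups, p = 0.654).

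**Figure D1:**
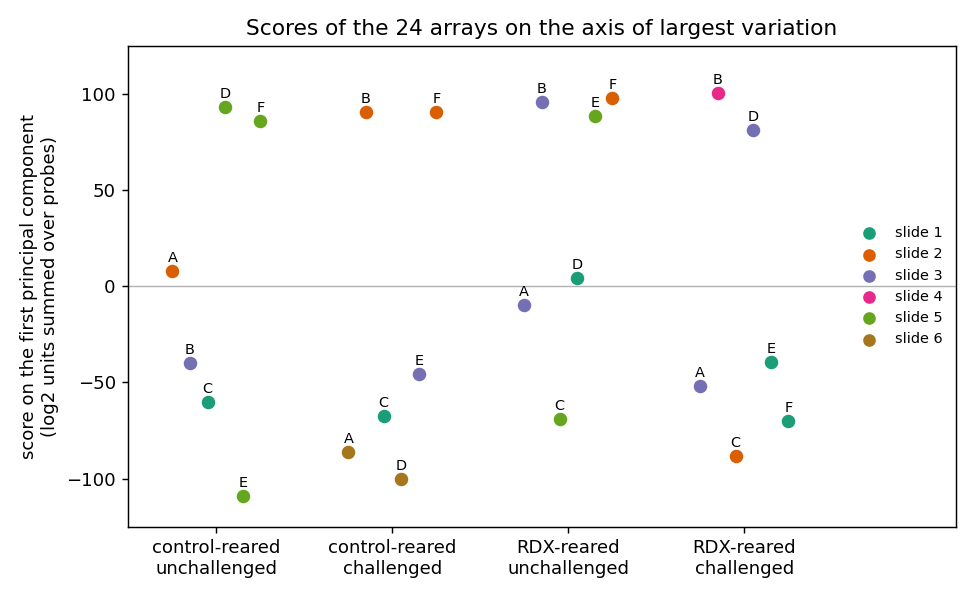
Score of each of the 24 arrays on the first principal component (vertical axis, log2 units summed over probes) by group, with replicate letters and with slides in colour. Each group holds arrays above 81.3 and arrays below 8.17, and none in between.

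The challenge of control-reared fish addressed the acute response of animals with no earlier exposure. No probe passed the threshold in limma (0 of 13537, lowest adjusted p = 1.00), and 171 had an unadjusted p under 0.05, of which 85 were higher and 86 lower in challenged fish. The 95% confidence interval of the difference excluded a 4-fold change in either direction for 11620 probes (85.8%), and its median distance from the estimate was 0.94 log2 units. Such intervals are unadjusted and concern measured signal. Of the tested probes, 9269 were well above background on all arrays. For dimmer or saturated spots the signal may understate a change in transcript level. The same limits hold for the intervals of the other contrasts. Probe UF_Ppr_AF_103405, which is described with the rearing effect, measured 0.93 ± 0.66 log2 units (SE) less signal after the challenge, which was within error (adjusted p = 1.00).

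The same challenge in RDX-reared fish gave 0 probes past the threshold in limma (lowest adjusted p = 0.900), with 442 at an unadjusted p under 0.05, 219 higher and 223 lower. The interval excluded a 4-fold change for 11221 probes (82.9%). This count was not stable to the weighting of arrays: with array quality weights, 2348 probes were called higher and 3707 lower, or 6055 in all, and the count returned to 0 when the first principal component entered that fit. Averaged over both lines, the challenge effect gave 0 probes in limma (lowest adjusted p = 0.925), with 374 at an unadjusted p under 0.05 and 3140 past the threshold with array weights. For the average effect the interval excluded a 4-fold change for 12620 probes (93.2%).

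Lines were bred apart, so exposure and ancestry cannot be separated in their challenge responses, and SE and p measure the spread among fish. Within that limit, the interaction of rearing and challenge addressed the stated question, as the difference between the challenge effects of the lines. It gave 0 probes past the threshold in limma (lowest adjusted p = 1.00). An unadjusted p under 0.05 was seen for 141 probes, fewer than the 677 that an even spread of p-values would give. That count changed with the fit. It was 99 of 9269 for probes well above background on all arrays, 492 with the first principal component as a covariate and 2400 with array weights. On the 3 complete slides it was 1102 of 13520, with slide as a fixed block. Each of these fits called 0 probes, and the unadjusted count says little about the interaction. The interval of the interaction excluded a 4-fold difference between the challenge responses for 8600 probes (63.5%). For UF_Ppr_AF_103405 the interaction was 0.01 ± 0.93 log2 units (SE). For UF_Ppr_AF_105393, which was not well above background in control-reared fish, no value of the interaction is given (limma, adjusted p = 1.00).

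The effect of rearing averaged over challenged and unchallenged fish was the contrast in which probes passed: 2 were higher in RDX-reared fish and 0 lower. Rearing was applied to breeding lines and not to single fish. Every SE and p given for rearing or for the interaction therefore measures the spread among fish, not among lines. UF_Ppr_AF_103405 was 2.96 ± 0.47 log2 units (SE, n = 12 against 12) higher in RDX-reared fish, which is 7.76-fold (limma, adjusted p = 0.0262). Its sequence is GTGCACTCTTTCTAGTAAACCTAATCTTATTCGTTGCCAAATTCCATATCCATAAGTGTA, with 35% G and C. Its log2 signal was -5.17 ± 0.68 in control-reared and -2.22 ± 1.65 in RDX-reared unchallenged fish, and -6.10 ± 0.64 and -3.14 ± 1.45 in the challenged fish of those lines (SD, n = 6 each). The rearing difference was thus 2.95 ± 0.66 in unchallenged and 2.96 ± 0.66 in challenged fish (SE). It was well above background in all 12 RDX-reared fish, in 5 of 6 control-reared unchallenged and in 4 of 6 control-reared challenged fish, so the fold rests in part on control values near background. Of the 12 RDX-reared fish, 10 lay above every control-reared fish. RDX-reared unchallenged replicate C, at -5.43, and RDX-reared challenged replicate E, at -4.80, lay inside the control-reared range of -6.70 to -4.42.

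UF_Ppr_AF_105393, with the sequence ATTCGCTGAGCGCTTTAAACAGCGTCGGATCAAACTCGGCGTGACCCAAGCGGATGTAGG (55% G and C), was also higher in RDX-reared fish on average (limma, adjusted p = 0.0343). It was not well above background in any of the 12 control-reared fish, and was so in 3 of 6 RDX-reared unchallenged and 6 of 6 RDX-reared challenged fish. Relative to that background, its mean signal was at least 3.82-fold higher in RDX-reared than control-reared challenged fish. In unchallenged fish the mean was at least 1.37-fold higher. Both bounds compare group means and allow for no sampling error. The unchallenged bound is 0.46 log2 units, less than the SE of 0.56 of the measured difference, and its brighter mean includes fish not well above background. Measured means were -7.15 ± 1.24 and -5.53 ± 1.35 in unchallenged and -7.16 ± 0.48 and -4.12 ± 0.63 in challenged fish, control-reared before RDX-reared (SD, n = 6 each). Of the 12 RDX-reared fish, 9 lay above every control-reared fish, and replicate C of the unchallenged ones again measured a control-like value, -8.14.

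Arrays of both lines shared slides 1, 2, 3 and 5. RDX-reared minus control-reared differences of UF_Ppr_AF_103405 within those slides were 2.16, 3.42, 2.75 and 1.98 log2 units. The mean of UF_Ppr_AF_105393 was at least 4.82-fold, 1.68-fold and 2.56-fold higher in RDX-reared fish within slides 1, 2 and 3. It was well above background there on 3 of 3, 1 of 2 and 3 of 4 RDX-reared arrays, and these bounds too allow for no sampling error. Within slide 5 the RDX-reared mean of the probe did not exceed the background bound. That slide held 2 RDX-reared arrays; without replicate C, chosen after its values were seen, UF_Ppr_AF_105393 was at least 2.39-fold higher there and UF_Ppr_AF_103405 was 4.15 log2 units higher. With slide as a fixed block the average difference of UF_Ppr_AF_103405 was 2.54 ± 0.46 (SE), and neither probe passed (limma, adjusted p = 0.405 for UF_Ppr_AF_103405 and 0.500 for UF_Ppr_AF_105393). Both passed with slide as a random block (limma, adjusted p = 0.0269 and 0.0333) and with the fixed block on the 3 complete slides (limma, adjusted p = 0.0379 for each). Replicate C lay on slide 5, so the fit on the 3 complete slides also left out its low values. That fit is therefore no separate check of slide alone. With normexp background correction and quantile normalization the average difference of UF_Ppr_AF_103405 was 1.91, and neither probe passed (limma, adjusted p = 0.0524 and 0.166).

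No probe was called lower in RDX-reared fish. The lowest p in that direction belonged to UF_Ppr_AF_109459, with the sequence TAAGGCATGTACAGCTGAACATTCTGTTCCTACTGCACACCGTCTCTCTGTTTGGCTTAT. Its average difference was -0.94 ± 0.18 log2 units (SE, limma, adjusted p = 0.117), and the call would have passed with quantile normalization (-1.10, adjusted p = 0.0385). Its signal was well above background on all 24 arrays, at -3.23 ± 0.30 and -4.19 ± 0.47 in unchallenged and -2.84 ± 0.38 and -3.76 ± 0.48 in challenged fish, control-reared before RDX-reared (SD, n = 6 each).

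**Figure D2:**
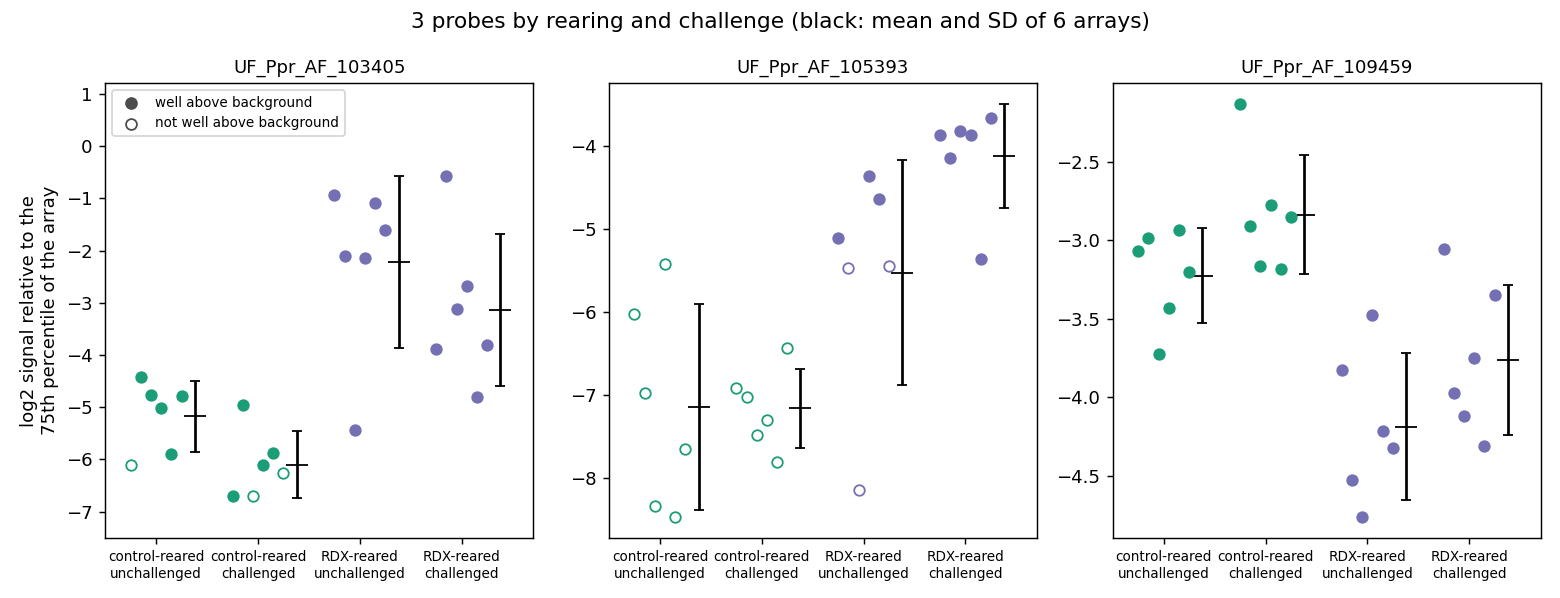
Log2 signal relative to the 75th percentile of the array (vertical axis, separate scale per panel) for 3 probes in the 4 groups. Each point is 1 fish, open where the probe was not well above background, and black marks give the mean and SD of 6 fish; UF_Ppr_AF_105393 is open in all 12 control-reared fish.

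Taken separately, neither challenge state gave a probe past the threshold for rearing. In unchallenged fish 404 probes had an unadjusted p under 0.05 (0 past the threshold in limma, lowest adjusted p = 0.960), 274 higher and 130 lower in RDX-reared fish. In challenged fish 543 did (0 past the threshold in limma, lowest adjusted p = 0.208, for UF_Ppr_AF_105393), 393 higher and 150 lower. For the average effect 748 did, 550 higher and 198 lower. That lean to higher values depended on scaling: the median difference of all probes was 0.07 log2 units for the average effect, and with quantile normalization the median was 0.01 and the same threshold gave 551 higher and 438 lower. The interval of the average rearing effect excluded a 4-fold difference for 12667 probes (93.6%).

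**Figure D3:**
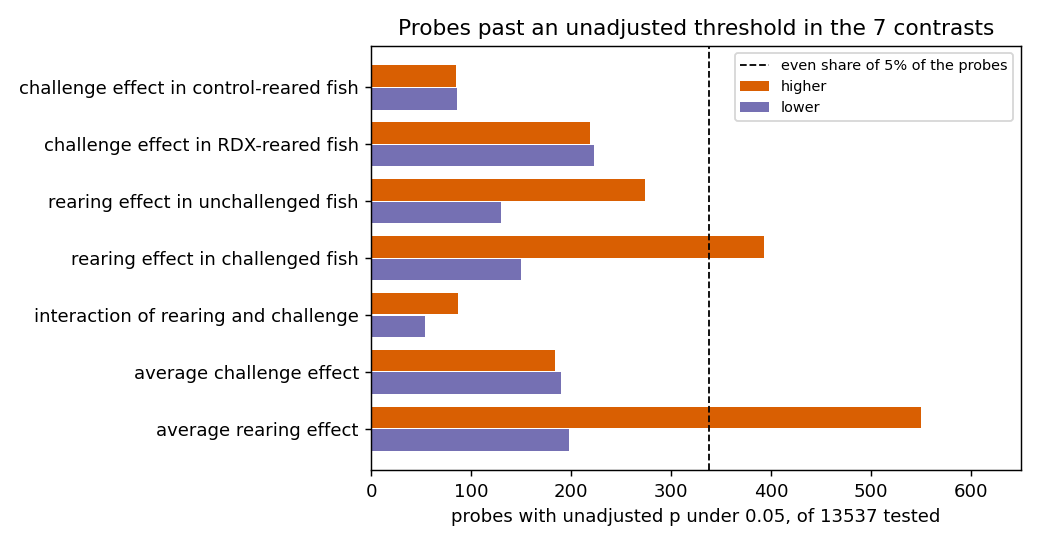
Number of probes (horizontal axis) with an unadjusted p under 0.05 in each of the 7 contrasts, split by direction, out of 13537 tested. The dashed line marks an even share of 5% of the probes between the directions; the interaction has 87 higher and 54 lower, and the average rearing effect 550 and 198.

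Over whole profiles, rearing held 5.03% of the variance, challenge 4.11% and their interaction 2.46%, against 4.35% for any single term by chance. Together they held 11.6% (permutation test, p = 0.542), and the p-values of the terms were 0.274, 0.391 and 0.765. Slide held 30.5%, against 21.7% by chance (permutation test, p = 0.0633).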

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

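The fits with array weights and with slide as a block, and the splits, were set down before their results were seen; the values within slides and the tests with the axis score, of labels and without 1 array were chosen after the data had been seen. A lone fish far from the other 5 of its group was looked for in 24 sets of 6 values, where chance would give about 1.2. It was found 3 times, always as the lowest fish of an RDX-reared group. All were in the probes called for their rearing difference on these same arrays, and replicate C gave more than 1 of them. The figure of 1.2 assumes unselected and independent sets, so it is no valid baseline here. In RDX-reared unchallenged fish, replicate C measured -5.43 for UF_Ppr_AF_103405 against -2.14 for the nearest fish, and -8.14 for UF_Ppr_AF_105393 against -5.48. Neither of these values of UF_Ppr_AF_105393 was well above background, so the size of that gap is uncertain. In RDX-reared challenged fish, replicate E measured -5.36 for UF_Ppr_AF_105393 against -4.15.

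RDX-reared unchallenged replicate C thus lay at the level of control-reared fish for both probes that were called. RDX-reared challenged replicate E, at -4.80, also lay inside the control-reared range for UF_Ppr_AF_103405. An exchange of labels with a control-reared fish would leave a control-reared array at the level of the RDX-reared ones, and 0 control-reared arrays lay inside the range of the other 11 RDX-reared arrays for both probes. Both probes were called on these same arrays for low control-reared and high RDX-reared values, so this check does not settle an exchange. A wrong label without such a partner also stays open. In UF_Ppr_AF_109459 the same array measured -4.76, the lowest of its group and far from the control-reared fish. That probe too was chosen by its rearing difference on these arrays. Without RDX-reared unchallenged replicate C the average rearing effect kept both probes (limma, adjusted p = 0.000176 and 0.000386). UF_Ppr_AF_103405 was then at 3.28 ± 0.37 log2 units (SE) and passed in unchallenged fish alone. The array was left out for its low values in both called probes, so its removal was bound to raise their rearing differences. The fit without it is therefore no independent test of the rearing effect. A real difference between fish of the RDX-reared line may equally account for the low values of this array, and was not tested.

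For UF_Ppr_AF_103405, RDX-reared fish were higher within 4 of 4 slides that held both lines, which argues against slide or scan day as the whole source of its rearing difference. For UF_Ppr_AF_105393 the RDX-reared mean exceeded the background bound of control-reared fish within 3 of 4 slides. On the other, slide 5, 1 of the 2 RDX-reared arrays was replicate C, without which the probe was at least 2.39-fold higher there. It passed with the fixed block on the 3 complete slides (limma, adjusted p = 0.0379) but not on all slides (limma, adjusted p = 0.500). The 3 complete slides do not hold replicate C. In the fit on all slides the difference of UF_Ppr_AF_105393 did not shrink and its SE rose from 0.39 to 0.47. Slide was not excluded as a contributor, since the RDX-reared mean exceeded the bound within only 3 of 4 slides. The slide that fell short held replicate C, so this count is no evidence of a slide effect either. With slide as a fixed block the difference of UF_Ppr_AF_103405 went from 2.96 ± 0.47 to 2.54 ± 0.46 (SE) and its limma statistic from 6.33 on 22.8 degrees of freedom to 5.55 on 17.8. The lower statistic would have missed the threshold as a lone call even at the former degrees of freedom. With the axis score as a covariate, the difference of UF_Ppr_AF_103405 was still 93.5% of its value, which argues against the axis as its whole source. A count of 2 probes was rare among splits of the rearing labels within challenge states. Only 1 of 100, the real one included, gave as many, and the highest other gave 1. That share is the lowest such a test can give, and the splits did not keep slide fixed. With slide as a fixed block the count was 0, so chance was not excluded. Exposure and ancestry cannot be separated by any of these tests, because each line was bred apart, and a variant under a probe that differed in frequency between the lines remains open and untested.

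The 6055 probes called with array weights for the challenge effect in RDX-reared fish may come from weights that differ along the shared axis. The weights moved the difference of mean axis scores between challenged and unchallenged RDX-reared fish from -45.8 to -117, and with the axis score added to the same weighted fit 0 probes were called in place of 6055. On the 12000 probes without a missing spot, 5313 were called with weights. Other splits of those 12 arrays gave up to 6734, 36 of them called over 1000, and 9 of 100 splits, the real one included, called as many, so chance was not excluded.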

How the results depend on the processing

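The first component as a covariate, alone or with array weights, the outlier spots kept and the fit without 1 array were chosen after seeing the data; the other alternatives were set before. Of 102 counts over the 7 contrasts, 87 stayed within 1.5 times the reported count and 15 did not. Array weights gave 6055 probes for the challenge effect in RDX-reared fish, 3140 for the average challenge effect, 9 for rearing in unchallenged fish, 2 for rearing in challenged fish and 6 for average rearing. The first component as a covariate gave 3 probes for rearing in challenged fish and 6 for average rearing, and together with array weights 2 and 13. Fitting only the 2 groups compared gave 1 for rearing in challenged fish, and leaving out RDX-reared unchallenged replicate C gave 1 for rearing in each challenge state. The average rearing effect had 0 probes with slide as a fixed block, with normexp and with probes well above background on all arrays. The last of these filters removed both called probes from the test; the offset of 50 compresses dim signals; apart from the weights and the slide block, the causes of the other changes were not tested.

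The average rearing difference kept its sign in all alternatives. It ranged from 1.91 to 3.28 log2 units for UF_Ppr_AF_103405 over 13 alternatives, with adjusted p from 0.000176 to 0.405, passing in 11. UF_Ppr_AF_105393, below background in control-reared fish, had adjusted p from 0.000386 to 0.500 and also passed in 11 of 13. For UF_Ppr_AF_109459 it ranged from -1.10 to -0.69 over 14, with adjusted p from 0.0385 to 1.00, passing in 3. Some alternatives could hardly change these values. The deposited table matched the values used, these probes had no marked spot, and dropping the filter on dim probes left their differences as they were. Replicate C was left out for its own values in the called probes, and the 3 complete slides did not hold it either. The counts of alternatives passed are thus no measure of independent support.

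The replicate letters were not taken to pair the fish: residual correlations of the 36 same-letter pairs had a median of 0.19, against -0.03 for other letters, but ran from -0.57 to 0.79, 20 were over 0.1, and 7 of 24 arrays correlated best with their own letter. With a replicate block the average rearing effect had 3 probes, adding UF_Ppr_AF_109459 (adjusted p = 0.0427), and the other 6 contrasts had 0. Gene lists and an estimated correlation between genes were not run, since probes had no gene names. For probes not well above background in a group, signal over background limits the values to bounds.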

Other observations

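The tests of correlated effects, of whole profiles and of the shared axis were chosen after the values were seen; those of spread, of contigs and of other splits of the arrays were set down before their results were seen. Pairs of probes whose source contigs share a stem in their identifiers varied together across the 24 fish. Over 885 such pairs the median correlation was 0.44, against 0.14 for random pairs, and 18.4% of the pairs exceeded 0.8, against 3.5% of random ones. This is consistent with such probes measuring related transcripts; many pairs still varied apart.

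The shared axis reached 3536 of the 12000 probes at a correlation with it of over 0.8 in size, 2042 of them positive and 1494 negative. The axis moved with array brightness: the 10 arrays with the lowest 75th percentile of signal held all 9 with scores above the gap. After quantile normalization, which removes array effects that depend on signal level alone, the first component still held 49.7% of the variance, against 48.1% before, and its scores correlated with the former ones at 0.995 in size. That argues against such a brightness effect as its source; whether both follow from the RNA content of the samples was not tested. The widest range of scores within a slide was 96.5% of the range over all arrays, which argues against slide or scan day, and the narrowest within a group was 79.8%, which argues against rearing or challenge as its main source. Sex, maturity and the organs contained in each sample are not given by the labels, and any of them may underlie an axis of this size; with no named genes this was not tested. The number of the 129 wide-ranging probes not well above background on an array, replicates A to F, was 11, 12, 17, 53, 36 and 56 in control-reared unchallenged fish and 12, 49, 15, 14, 12 and 60 in control-reared challenged fish. It was 7, 63, 15, 12, 31 and 54 in RDX-reared unchallenged fish and 12, 30, 6, 44, 17 and 13 in RDX-reared challenged fish.

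Counts of calls were also taken over other splits of the arrays. For the 6 contrasts with 0 called probes, 100 of 100 splits gave as many, as any split must, so this comparison says nothing about them. The highest other split called 2515 probes for the challenge effect in control-reared fish, 1 in RDX-reared fish, 3649 for rearing in unchallenged fish and 2152 in challenged fish. It called 1 for the interaction and 5312 for the average challenge effect. Each of the 4 counts over 1000 came from 1 split, the only one of its contrast above that number, and between 1 and 5 of the other splits of a contrast called any probe. Such counts were thus rare, and point to a structure of the samples only in those splits.

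Rearing effects in unchallenged and in challenged fish, which share no array, correlated at 0.31 across probes, which are not independent. Of 100 splits of the rearing labels within challenge states, 20 gave a correlation as large, with a highest other of 0.65. Challenge effects in the control-reared and RDX-reared lines correlated at 0.27, and 27 of 100 splits gave as much, with a highest other of 0.79. A shared effect of rearing or of challenge was therefore not seen beyond chance, and a small one is not excluded. The whole-profile test of rearing, challenge and interaction together likewise left room for small effects (permutation p = 0.542).

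The spread between fish was alike in the 4 groups within error. Mean distances of the 6 fish to the centre of their group were 103.6 ± 24, 105.1 ± 21.4, 95.4 ± 20.9 and 99.9 ± 25.2 log2 units in the order control-reared unchallenged, control-reared challenged, RDX-reared unchallenged and RDX-reared challenged (SD, n = 6 each; permutation p = 0.883). A p of this size excludes no small change in spread.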
